A study of Mus musculus with 4 samples.

How the data were processed

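RNA was taken from tdTomato-positive cells sorted from enzymatically dissociated dental follicles of mouse mandibular molars. Per the labels' protocols, total RNA was isolated with a PicoPure kit, cDNA was amplified with the SMART-Seq v4 ultra-low-input kit and libraries were made with Nextera XT. Sequencing was on an Illumina HiSeq 4000, per the series' design text. Whether the counting used strand is not given in the sources used here, so a gene and an antisense partner may share reads. Per the submitters' processing notes, the genome build was mm10 and the tools were FastQC, TopHat2 (2.0.13), Bowtie2 (2.2.1), Cufflinks, Cuffdiff, HTSeq and DESeq2, with no role or order given.

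The values used in the main test are a signal unit: gene counts that the authors divided by 1 factor per library, named scaled counts in the deposited table. How the authors set the factor is not given in the sources used here. In each library between 96.5% and 98.9% of the values below 100000 were whole multiples, within 0.1 of a read, of 1 step, and the rest were not, so that they are not whole reads throughout. A second deposited table holds FPKM values, made by the authors relative to transcript length and library size, and was used as an alternative. Both tables list 23107 genes. A further 16 columns of per-sample values, in 4 tables, carry names that match no label and were not used. The named columns count libraries from 0 and the sample titles from 1, so columns were given a group and not a sample. For each group the labels give 2 samples, and nothing says that they came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

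The scaled totals of 69361760 to 71228342 and the implied 62300000 to 85700000 reads per library make the error from counting reads small for most of the genes named. Reads of amplified cDNA do not show how many molecules were sampled. Library complexity differed more than these totals: cHet_1 had 34 genes at 0 that had at least 100 in each of the other 3 libraries, against 0, 3 and 3 such genes in cHet_0, cKO_0 and cKO_1. Genes at 0 were not confined to cHet_1. Within cKO, 250 genes were at 0 in cKO_0 with at least 100 in cKO_1, and 52 in reverse. Within cHet, 209 were at 0 in cHet_1 with at least 100 in cHet_0, and 20 in reverse. The precision of a comparison is set by the spread between libraries (median standard error 0.74 log2 units).

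The test planned before the data were examined was a negative binomial one on raw counts, which the usable tables do not hold. In its place limma (3.58.1, R 4.3.3) with a mean-variance trend was fitted to log2(scaled count + 3) for genes with a scaled count of at least 10 in at least 2 libraries, 14297 in all, with group as the only term. The pseudocount, this filter and the use of limma were set after the unit was known. Fold changes on this scale understate the change of low genes. Standard errors and p-values are limma's moderated ones: each gene's spread is drawn toward that of genes of like abundance. They can therefore exceed or fall below the spread of the gene's own values. P-values are two-sided and Benjamini-Hochberg adjusted, with 0.05 as threshold. The gene lists, the threshold and the rule for naming genes were fixed before the data were examined.

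Of 39 gene lists with 1179 entries, 1084 entries were matched to the tables by symbol or by a unique synonym in the mouse RefSeq annotation. Ribosomal protein and mitochondrially encoded transcripts had no matched members and were not analysed here. The other 37 lists, each with at least 5 tested members, were tested with camera (preset inter-gene correlation 0.01) and adjusted over the 37. Of the 12 calls, 0 held with an estimated correlation (lowest adjusted p 0.508) and 0 with fry (lowest adjusted p among them 0.632). With an estimated correlation, camera also takes its degrees of freedom from these few libraries, not from the number of genes. P-values therefore rose even for 4 lists with an estimate below the preset: collagens (-0.028), osteoblast genes (-0.001), secretory genes (-0.018) and odontoblast markers (-0.028). For the other called lists the estimate was above it, up to 0.567. A call lost there does not by itself show correlated genes. The number of members passing was also counted adjusted over each list alone. Gene coordinates are from GENCODE vM21 for the same assembly as mm10, 1-based.

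The rule always named a fixed set of 7 genes, among them Ptch1, Gli1, Hhip, Foxf1, Foxf2 and Pthlh; 1 of the set is not reported here. Since 0 genes passed in either direction, it then took the 5 with the lowest p in each direction, among genes whose groups did not overlap and whose mean was at least 10 CPM in the higher group, and up to 4 members with the lowest p of each list described. Most members that passed adjusted over a list alone are named as well. Xist, Ddx3y, Ambn, Cdh1 and Epcam are among the lowest-p members of their lists; other genes outside the rule were named after their values were seen.

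The limma step was tested on simulated libraries with these gene means. With the spread of these libraries, 0 of 99 genes changed 2-fold and 10 of 96 changed 4-fold were recovered at the threshold (10.4%), and with a fixed spread of 0.1 log2 units 99% and 100% were, for steps on 13664 and 14261 genes. Alternatives were other scalings (median of ratios, upper quartile, library totals), other filters, log2(FPKM + 1) and log2(FPKM + 0.1), leaving out each library in turn, an adjusted p of 0.1, and, chosen after seeing the data, pseudocounts of 1 and 30, limma in its robust form, without trend or with library quality weights, and a mean scaled count of at least 1000. Which list medians were followed through the alternatives was also decided after seeing the data: those of the 12 called lists and of the dental epithelium list. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.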

Results

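The series profiled cells of the dental follicle, the mesenchymal sheath around a developing tooth, from the mandibular molars of mice at postnatal day 8. The cells carried a tdTomato reporter that marks PTHrP-expressing follicle cells and were isolated by fluorescence-activated sorting after tamoxifen at postnatal day 3. With tamoxifen given before the day of collection, the reporter need not mean that a sorted cell still expressed PTHrP at postnatal day 8. Conditional heterozygotes for Ptch1 (cHet, n = 2 libraries) were set against conditional knockouts (cKO, n = 2 libraries). Ptch1 encodes the hedgehog receptor that holds the pathway off in the absence of ligand, so the comparison asks which transcripts differ in these cells when both copies rather than 1 are targeted. Libraries are named cHet_0, cHet_1, cKO_0 and cKO_1, as in the columns of the deposited tables. The scaled totals were 69361760, 71228342, 69677070 and 70698316 in that order, and the commonest count step corresponds to about 85700000, 68100000, 64700000 and 62300000 reads on genes. Genes with an FPKM of at least 1 numbered 12360, 9850, 12192 and 11355. Values below are scaled counts unless a log2 fold change (cKO minus cHet, on the log2(scaled count + 3) scale) is given, and ± is the standard deviation.

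Ptch1, the targeted gene (chromosome 13, 63508328 to 63573598, minus strand, mm10), was listed at 12870 and 5438 in the cHet libraries and at 22420 and 23340 in the cKO libraries, a log2 fold change of 1.45 (SE 0.39). The gene-level value covers the whole transcript, and Ptch1 is itself a hedgehog target, so it does not show by itself whether an exon was deleted. The pathway's standard readout, the transcription factor gene Gli1 (chromosome 10, 127329882 to 127341974), stood at 3740 ± 553 in cHet and 6670 ± 401 in cKO (log2 fold change 0.84, SE 0.34). Hhip, a hedgehog-binding inhibitor that the pathway induces (chromosome 8, 79965851 to 80058006), stood at 61500 ± 1210 in cHet and 168000 ± 10600 in cKO, 2.73-fold higher on the log scale. The forkhead genes Foxf1 (listed as Foxf1a; chromosome 8, 121084386 to 121088144) and Foxf2 (chromosome 13, 31625816 to 31631403) had log2 fold changes of 0.90 (SE 0.23) and 0.78 (SE 0.28), the latter 0.46 without cKO_0. All 5 of these genes lay higher in both cKO libraries than in both cHet libraries in scaled counts. In FPKM, Hhip overlapped between the groups, at 101 and 25.5 in cHet and 273 and 84.1 in cKO. Pthlh, which encodes PTHrP (chromosome 6, 147252101 to 147264183), overlapped between the groups at 12600 ± 4690 in cHet and 10400 ± 2580 in cKO (log2 fold change -0.24, SE 0.34). Its fold change was -0.63 without cHet_0, 0.15 without cHet_1, -0.49 without cKO_0 and 0.02 without cKO_1.

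None of these 6 genes passed the Benjamini-Hochberg threshold over all genes in limma; the adjusted p was 0.913 for each of Ptch1, Gli1, Hhip, Foxf1a and Foxf2, and the unadjusted limma p was 0.00602, 0.0387, 0.000267, 0.00484 and 0.0235 in that order. Among the 23 tested hedgehog target genes, 20 had higher values in cKO, with a median log2 fold change of 0.78 against 0.12 over all genes, and the list was called higher (camera adjusted p = 5.05e-05). With an estimated correlation the list's p was 0.197 (adjusted p = 0.7). Adjusted over the list alone, 4 members rose, among them Hhip, Foxf1a and Ptch1, against 0 over all genes tested. The list was called whichever single library was left out, but its median was 0.18 without cHet_1 and 0.46 without cKO_0. The Ptch1 log2 fold change was 2.07 without cHet_0 and 0.83 without cHet_1.

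**Figure D1:**
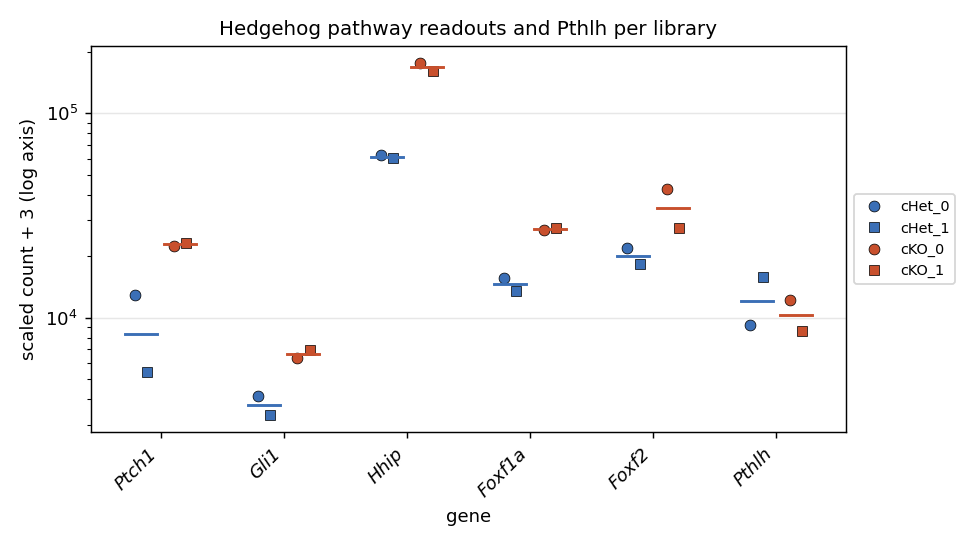
Scaled count plus 3 on a log axis for 6 genes in each library; blue symbols are cHet, orange symbols cKO, circles the libraries numbered 0 and squares those numbered 1, and each bar is the group mean of the log values (n = 2). The cKO symbols lie above the cHet symbols for Ptch1, Gli1, Hhip, Foxf1a and Foxf2 and overlap with them for Pthlh.

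Across the 14297 genes tested, limma called 0 genes higher and 0 lower in cKO at an adjusted p under 0.05, and the lowest adjusted p was 0.913. At an unadjusted p under 0.05 there were 220 genes higher and 213 lower, where 715 would be expected by chance. The groups did not overlap for 2576 genes higher and 2032 lower in cKO, 32.2% of those tested, where chance gives 33.3% for 2 libraries against 2. Library cHet_1 correlated with cHet_0 at 0.791 and with cKO_0 and cKO_1 at 0.753 and 0.742 (Pearson, across genes, log2 scale). Library cHet_0 correlated with cKO_0 at 0.893 and with cKO_1 at 0.858, and cKO_0 with cKO_1 at 0.811. The highest correlations were thus between groups, and the libraries did not pair by genotype. The count depended on the libraries: 1061 genes were called higher and 78 lower without cHet_0, 0 and 0 without cHet_1, 7 and 5 without cKO_0, and 10 and 32 without cKO_1.

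The genes with the lowest p in each direction are given as values, since none passed. On the higher side were Sostdc1, a secreted BMP and Wnt antagonist (chromosome 12, 36314139 to 36318452), at 22100 ± 6570 in cHet and 73300 ± 262 in cKO; Fstl4 (chromosome 11, 52764634 to 53188538) at 7170 ± 498 and 22700 ± 4370; Hhip; Aldh1a3, a retinoic acid synthesis enzyme (chromosome 7, 66390890 to 66427517), at 33400 ± 4340 and 82300 ± 12000; and Mmp9, a matrix metalloproteinase (chromosome 2, 164940780 to 164955850), at 2050 ± 453 and 9580 ± 3190. Their log2 fold changes were 1.76, 1.65, 1.45, 1.30 and 2.2, with unadjusted limma p from 0.000163 for Sostdc1 to 0.000636 for Mmp9. On the lower side, the fibrillar collagen gene Col24a1 (chromosome 3, 145292472 to 145552011) stood at 10500 ± 121 in cHet and 1220 ± 410 in cKO, a log2 fold change of -3.14 (SE 0.43). Its unadjusted limma p was 7.67e-05, the lowest of these 10 genes, and its adjusted p 0.913. Plod2, a collagen lysyl hydroxylase (chromosome 9, 92542223 to 92608428), stood at 29200 ± 3220 and 9790 ± 2250. The matrix glycoprotein gene Tnn (chromosome 1, 160085029 to 160153580) stood at 17300 ± 10100 and 3110 ± 617. The proteoglycan gene Dcn (chromosome 10, 97479609 to 97518143) stood at 50500 ± 5390 and 21400 ± 2580. Sp6, a transcription factor gene of tooth development (chromosome 11, 97013394 to 97024734), stood at 52100 ± 14000 and 13800 ± 7410. The log2 fold changes of Plod2, Tnn, Dcn and Sp6 were -1.59, -2.35, -1.24 and -2.0.

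Collagen genes and osteoblast genes were called lower in cKO as lists. Col1a1, Col1a2 and Col5a2 belong to both, and Col12a1 and Col14a1 to the collagen and dental follicle lists. Smpd3 and Phex belong to the osteoblast and odontoblast lists. These lists, all called lower, are therefore not independent. Of 18 fibrillar and fibril-associated collagens, 13 had lower values (median log2 fold change -0.43, camera adjusted p = 0.00019), and 4 fell when adjusted over the list alone, Col24a1, Col12a1 (-1.31; -0.81 without cHet_1), Col11a1 (-0.95) and Col27a1 (-1.29), against 0 over all genes. With an estimated correlation the collagen list's p was 0.0412 (adjusted p = 0.508). The main bone collagen gene Col1a1, named after its values were seen and the most abundant gene in 3 of the libraries, was listed at 3673000 and 3371000 in cHet and at 2122000 and 2100000 in cKO (log2 fold change -0.74, SE 0.58). Its values lay close together within each group, so this SE comes mostly from limma's moderation. Of 34 osteoblast and cementoblast genes, 22 had lower values (median -0.25, camera adjusted p = 0.000264). In this list 0 passed adjusted over the list alone and 0 over all genes, and the p was 0.0403 (adjusted p = 0.508) with an estimated correlation. Its members with the lowest p were Smpd3, a sphingomyelinase needed for mineralisation (-1.71, SE 0.40; -1.12 without cHet_0), Phex, a phosphate-regulating peptidase (-4.11, SE 1.11), Enpp1, a pyrophosphate-generating enzyme (-1.15, SE 0.54), and Bglap, osteocalcin (-2.35, SE 1.13). The osteoblast transcription factor genes Runx2 and Sp7, named here after their values were seen, had log2 fold changes of 0.05 (SE 0.24) and 0.03 (SE 0.38). Both lists were called whichever single library was left out. The collagen median lay between -0.57 and -0.22 and the osteoblast median between -0.48 and -0.18 over all the alternatives, with the collagen median at -0.22 without cHet_1 and the osteoblast median at -0.48 without cKO_1.

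Dental follicle and periodontal ligament markers were called lower (26 tested, 17 with lower values, median -0.36, camera adjusted p = 0.00701; p = 0.149 and adjusted p = 0.7 with an estimated correlation). Adjusted over the list alone, 6 fell, Tnn, Dcn, Lum (-1.08), Col12a1, Sfrp4 (-1.48) and Postn (-1.03), and 1 rose, Bicc1 (0.86); over all genes 0 passed. Lum and Postn encode matrix proteins of ligament and follicle, and Sfrp4 a secreted Wnt antagonist. Without cHet_1, Postn was at -0.66 and Col12a1 at -0.81, the median was -0.03 and the list was not called (adjusted p = 0.175), and without cKO_1 the median was -0.04. Among genes with a mean scaled count of at least 1000 the list was not called either (median -0.29, adjusted p = 0.0558). Dental papilla and odontoblast markers were called lower (20 tested, 12 with lower values, median -0.51, camera adjusted p = 0.00502; p = 0.069 and adjusted p = 0.639 with an estimated correlation), and adjusted over the list alone Sp6, Smpd3, Cd24a (-1.14), Phex and Dspp (-4.91) fell, against 0 over all genes. Dspp, the dentin sialophosphoprotein gene of odontoblasts, was listed at 27940 and 69630 in cHet and at 229.5 and 9251 in cKO, so that the cKO libraries also differed from each other. That list was not called without cHet_0 (median -0.17, adjusted p = 0.189), and its median was -0.12 without cKO_1.

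Endoplasmic reticulum stress and secretory genes were called lower as a list (32 tested, 24 with lower values, median -0.26, camera adjusted p = 0.000264), with 0 members passing adjusted over the list alone or over all genes. With an estimated correlation their p was 0.0401 (adjusted p = 0.508), and with log2(FPKM + 1) and no filter the list was not called (median -0.19, adjusted p = 0.0559). Its members with the lowest p were the secretory transcription factor genes Xbp1 (-0.62, SE 0.23) and Creb3l1 (-0.56, SE 0.24), the translocon gene Ssr1 (-0.57, SE 0.25) and Herpud1 (-0.89, SE 0.40). Ssr1 and Herpud1 were at -0.37 and -0.46 without cKO_1.

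**Figure D2:**
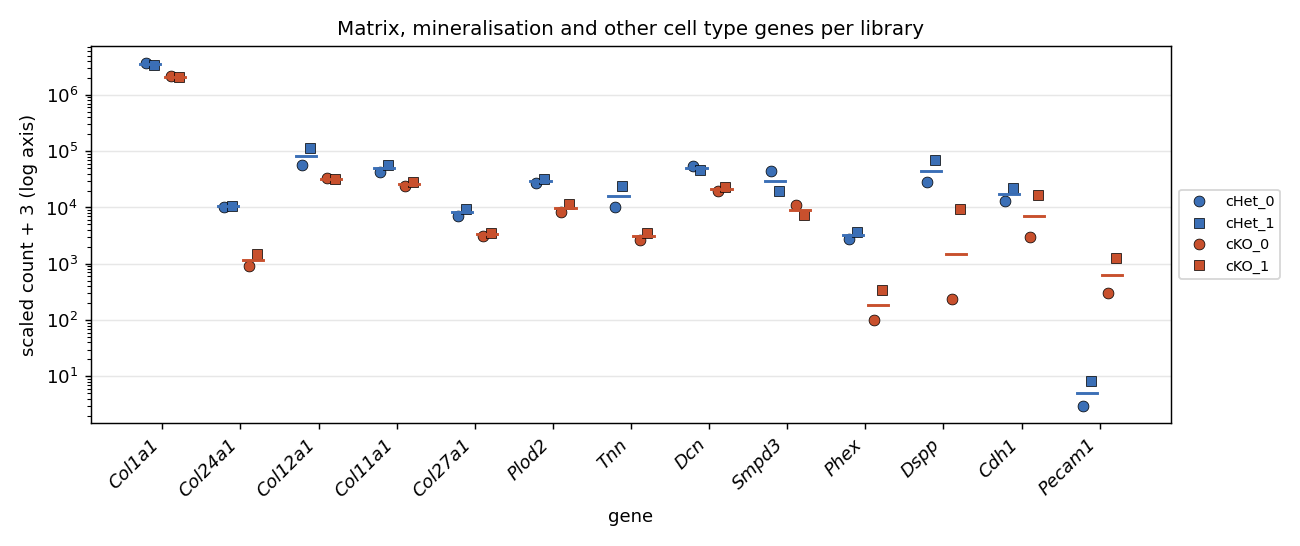
Scaled count plus 3 on a log axis for 13 matrix, mineralisation and other cell type genes in each library; colours, symbols and bars mark groups, library numbers and group means of the log values as in the plot of hedgehog genes (n = 2 per group). Col24a1 lay near 10500 in both cHet libraries and at 927.6 and 1507 in the cKO libraries, whereas Dspp and Cdh1 differed between the cKO libraries.

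Forkhead transcription factor genes were called higher (20 tested, 15 with higher values, median 0.77, camera adjusted p = 0.00701; p = 0.118 and adjusted p = 0.7 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Of the tested forkhead genes, 6 belong to the hedgehog target list too, Foxf1a, Foxf2 and Foxc2 among them, so that the lists are not independent. The other member among the lowest p was Foxq1 (log2 fold change 1.04, SE 0.31; 0.61 without cHet_1). The forkhead list was not called without cHet_0, although its median was 0.93 there (adjusted p = 0.189), and its median was 0.45 without cHet_1. Interferon response genes were called higher (29 tested, 25 with higher values, median 0.82, camera adjusted p = 0.000364; p = 0.206 and adjusted p = 0.7 with an estimated correlation), and 0 members passed adjusted over the list alone or over all genes. Several members were nearly missing from cHet_1: Gbp2, a guanylate-binding protein gene, was listed at 1020 and 15.7 in cHet and at 2907 and 1935 in cKO, Psmb8, an immunoproteasome subunit gene, at 475.3 and 11.51 against 1303 and 1998, and Cmpk2 at 829.2 and 21.98 against 2905 and 1627. Oasl2 stood at 1433 and 1184 against 2558 and 3488. Without cKO_1 the interferon list was not called (median 0.97, adjusted p = 0.0545), and without cHet_0 its median was 1.33.

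Markers of other cells differed with the groups or with single libraries. Endothelial markers were called higher (17 tested, median 2.02, camera adjusted p = 0.0098; p = 0.35 and adjusted p = 0.7 with an estimated correlation) at low levels: Pecam1 was listed at 0 and 5.233 in cHet and at 299.5 and 1278 in cKO, and Cdh5 at 40.49 and 69.07 against 470.8 and 873.7. Schwann cell and neuronal markers were called higher (14 tested, median 1.69, camera adjusted p = 0.0339; p = 0.444 and adjusted p = 0.703 with an estimated correlation), with S100b at 754.7 and 432.2 against 2607 and 2890, Prx at 1080 and 58.6 against 2615 and 3675, and the neuronal tubulin gene Tubb3 in the other direction at 4495 and 4048 against 1336 and 1441. Dissociation and immediate early genes were called higher (31 tested, 26 with higher values, median 0.34, camera adjusted p = 0.00245; p = 0.377 and adjusted p = 0.7 with an estimated correlation). The members with the lowest p included Btg2 (1.02, SE 0.36), Klf2 (0.84, SE 0.30) and the chaperone gene Dnajb1 (0.66, SE 0.27). Btg2 was at 0.62 without cHet_1 and 0.61 without cKO_1, and Klf2 at 0.55 without cKO_1. The list made up 1.89%, 1.92%, 1.96% and 3.02% of the scaled counts in cHet_0, cHet_1, cKO_0 and cKO_1. In each of these 3 lists 0 members passed adjusted over the list alone or over all genes. Without cKO_1 none of the 3 was called (adjusted p = 0.818, 0.927 and 0.723, medians 0.11, 0.29 and 0.05), nor without cHet_0 (adjusted p = 0.227, 0.0776 and 0.464, medians 3.16, 2.96 and 0.35). Their medians were 0.93, 0.59 and 0.38 without cHet_1 and 4.31, 3.13 and 0.7 without cKO_0. The endothelial list was not called among genes of at least 10 CPM (median 0.22, adjusted p = 0.953) or with a mean scaled count of at least 1000 (0.30 and 0.777). The Schwann cell list was not called there either (adjusted p = 0.053 and 0.0984), but its median did not fall (1.69 and 2.26).

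Dental epithelium markers were abundant in every library and were not called (30 tested, median 0.04, mean 0.53, camera adjusted p = 0.793, direction lower). The enamel matrix gene Ambn was listed at 165600 and 394100 in cHet and at 376000 and 976100 in cKO, whereas the epithelial cadherin gene Cdh1 stood at 13280 and 22010 against 2955 and 16350, and Epcam at 4828 and 2448 against 620.6 and 1002. Without cKO_0 the epithelium list was called higher (median 1.08, adjusted p = 5.24e-10), and without cKO_1 it was called lower (median -0.98, adjusted p = 1.04e-14). The 5 tested sex-linked genes were called lower as a list (median -1.18, camera adjusted p = 0.0408; p = 0.231 and adjusted p = 0.7 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Its X-linked member Xist, the transcript of the inactive X, was listed at 4319 and 102.6 in cHet and at 6489 and 5596 in cKO. The Y-linked gene Ddx3y was listed at 4778 and 8313 against 3942 and 1971, so that every library held transcripts of both kinds in differing proportions. The sex-linked list was called in 7 of 17 alternatives. With all 4 libraries it was not called with median-of-ratios scaling (adjusted p = 0.0653, median -1.28), no filter (0.125, -0.89), 10 CPM (0.134, -1.18) or library weights (0.0717, -1.18). Nor was it called with the 3 FPKM settings (adjusted p = 0.108, 0.13 and 0.188, medians -0.81, -1.03 and -0.62). It was not called without cHet_0, cHet_1 or cKO_1 either (adjusted p = 0.256, 0.142 and 0.402, medians -1.58, -0.78 and -0.68).

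The other 25 of the 37 lists tested, the epithelial one included, were not called, with camera adjusted p from 0.0513 for matrix proteoglycans and glycoproteins to 0.934. Single members of 6 of them passed adjusted over their list alone and not over all genes. Sostdc1 rose within the Wnt list, Mmp9 within both the osteoclast and the protease lists, and Col9a2 (1.16, SE 0.27) within the chondrocyte list, in which Hapln1 (-1.53, SE 0.39) fell. Dcn fell within the proteoglycan list and P4ha2, a collagen prolyl hydroxylase (-2.18, SE 0.46; -1.45 without cKO_0), within the glycolysis and hypoxia list. Leukocyte, pericyte, erythroid and skeletal muscle markers had camera adjusted p of 0.567, 0.544, 0.154 and 0.544, and cell cycle genes 0.154.

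**Figure D3:**
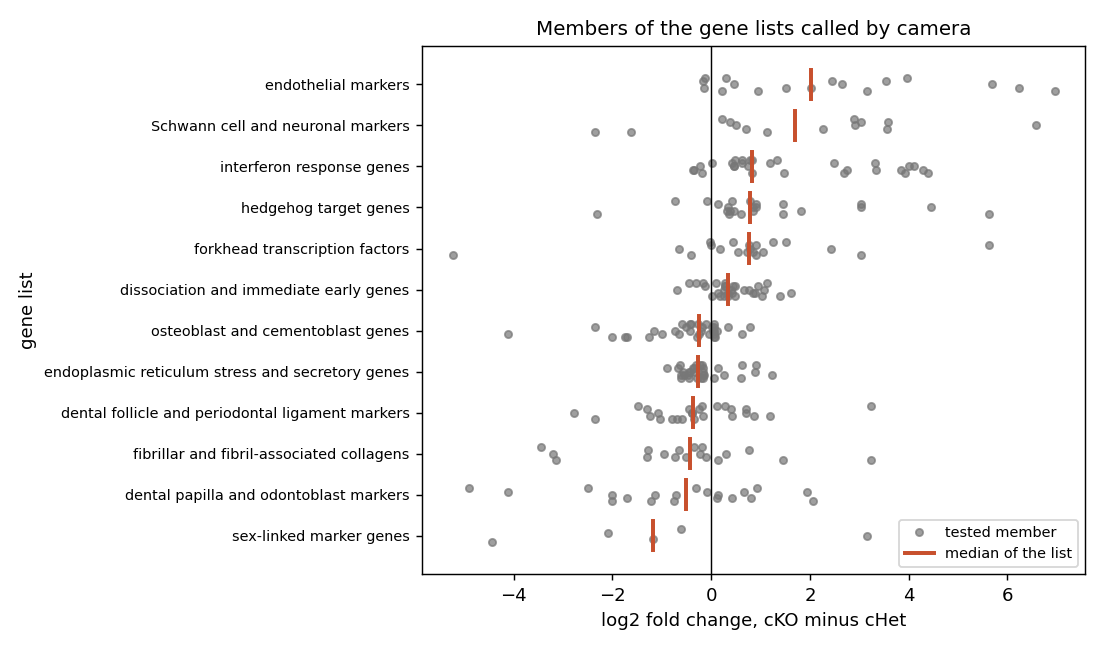
Log2 fold change (cKO minus cHet) of each tested member, as grey points, for the 12 gene lists called by camera with its preset correlation, with the list's median as an orange bar. Medians ran from -1.18 for sex-linked marker genes to 2.02 for endothelial markers, and members of every list lay on both sides of 0.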

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

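Pseudocounts, limma's robust, untrended and weighted forms and the filter at a mean of 1000 were chosen after seeing the data. The other alternatives were planned. The library quality weights were 0.68 for both cHet and 1.47 for both cKO libraries, so the weighted form could not set cHet_1 apart from cHet_0. The counts of 0 genes higher and 0 lower held under every scaling, filter, pseudocount and form of limma run on scaled counts and at an adjusted p of 0.1. They were 3 (Mir212, Snord65 and Prg2) and 4 (Snord83b, Mir1901, Mir214 and Dspp) with log2(FPKM + 1), and 1 (Mir212) and 1 (Snord83b) with log2(FPKM + 0.1). Leaving out 1 library gave 0 to 1061 genes higher and 0 to 78 lower; the lone library of a group is then assumed to vary like the pair of the other group. The cause was not tested. Without cKO_0 the 5 lower genes included Col24a1, Dspp, Smpd3 and Tnn. Lists called numbered 7 to 18 with 1 library left out, against 12 with all, 9 to 15 under the other settings that kept camera's preset correlation, and 0 with an estimated correlation and 0 with fry. Ptch1 ranged from 0.83 to 2.07 with 1 library left out, passing only without cHet_0 (adjusted p = 0.0143; 0.0143 to 1 over the alternatives), and Gli1 from 0.69 to 0.99. Of 1384 values of 78 genes, 1337 kept their direction and side of the threshold, 45 came to pass it and 2 changed sign. None of these genes passed in the main fit, so keeping a side meant only that a gene still did not pass. Filters on scaled counts and the robust, untrended and weighted forms of limma left each fold change as it was, so no sign could change there. Both changes of sign were of Pthlh, which ranged from -0.63 to 0.15 with 1 library left out (0.15 without cHet_1, 0.02 without cKO_1). The immediate early list's test turned to lower without cKO_1, with medians of 0.05 to 0.7 over the left-out libraries. The dental epithelium list's test turned with log2(FPKM + 1) (median -0.07), with fry (0.04) and without cHet_1 (-0.1) or cKO_0, with medians of -0.98 to 1.08 over the left-out libraries; the causes were not tested. Hedgehog target, collagen and osteoblast lists were called in 18 of 18 alternatives that kept camera's preset correlation. The endothelial list was not called when low genes were removed (median 0.22, adjusted p = 0.953 at 10 CPM; 0.30 and 0.777 at a mean of 1000). Median-of-ratios scaling moved the median over all genes from 0.12 to 0.02. No paired analysis was possible because the columns could be matched to a group but not to a sample, so they carry no replicate number from the labels; the planned replicate block was therefore not run. A block on the column numbers 0 and 1 was not fitted, as nothing states that they pair libraries. Still, FPKM went with that number for some genes with like scaled counts within a group. Hhip was at 101 and 273 in the libraries numbered 0 and at 25.5 and 84.1 in those numbered 1. Foxf1a was at 258 and 474 against 470 and 890, while Gli1 (16.2 and 25.8 against 14.4 and 30.5) showed no such split. Its cause was not tested. Not run, for want of usable raw counts, were the planned count-based tests with their trimmed-mean scaling, robust and earlier variants, and the other count table. With the spread of these libraries a 2-fold change of a single gene is below what the test recovers, so a gene that did not pass may still differ.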

Other observations

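All tests of explanations in this part, and the genes singled out in its first paragraphs, were chosen after the values were seen, and none of these genes passed over all genes in limma. Cyp26a1, which encodes a retinoic acid-degrading enzyme, stood at 6695 and 8986 in cHet and at 616.3 and 2722 in cKO. Shh, a hedgehog ligand gene, stood at 6137 and 6738 in cHet and at 649.7 and 2875 in cKO. The Wnt ligand genes Wnt6 (log2 fold change -1.69, SE 0.45; -1.11 without cKO_0) and Wnt10a (-1.38, SE 0.37) lay lower in cKO, while Wnt2b was listed at 10.53 and 3.14 in cHet and at 504.2 and 721.7 in cKO. The hedgehog pathway components list, which holds Shh, was not called (camera adjusted p = 0.695). Shh, Cyp26a1, Wnt6 (1774 and 3989) and Sp6 (8564 and 19050) lay lower in cKO_0 than in cKO_1. So did the epithelial gene Cdh1 (2955 and 16350), while Wnt10a differed little (2264 and 2516). In cKO_1 the first 4 still lay below both cHet libraries, and Cdh1 did not. The epithelial marker Epcam did, at 1002 in cKO_1 against 4828 and 2448 in cHet. Of 23 epithelium markers with a mean scaled count of at least 1000, 2 lay below both cHet libraries in cKO_1 and 13 above both. Whether these values follow the share of epithelial RNA was not tested.

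A few genes were nearly absent from one group. Under 20 in both cHet libraries and over 300 in both cKO libraries were 7 genes, and 5 (Amd1, Atp6v0c, Ccdc17, Gldc and Lrrtm3) in the reverse direction; the other ways of pairing the 4 libraries gave 0 to 27. Prg2 and Epx, which encode granule proteins of eosinophils, were listed at 7.288 and 9.419 and at 4.049 and 9.419 in cHet and at 2804 and 1691 and 2631 and 297.3 in cKO. Amd1 was listed at 2622 and 1699 in cHet and at 1.976 and 1.692 in cKO, and Amd2 at 168.7 and 0.6818 against 3546 and 4768. Of the 50-base words in annotated Amd2 transcripts, 85.7% also occur in Amd1 transcripts, so the split between these genes is uncertain. Their sum was 2790 and 1700 in cHet and 3548 and 4769 in cKO.

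Hedgehog target genes lay higher in cKO. Low complexity of cHet_1 stays open. Without that library the list was still called at camera's preset correlation (adjusted p = 9.67e-05), but its median went from 0.78 to 0.18. Only cHet_0 then stands for its group, so this fit cannot decide. With all libraries the call was not kept with an estimated correlation (adjusted p = 0.7). That result includes cHet_1 and does not bear on this explanation. A different mix of male and female cells cannot be told apart from the group difference: the cHet libraries, which differ in Xist more than the group means do, differed over the list by a median of 0.38 (quartiles 0.16 and 2.15), a spread that includes the 0.78 between groups. The genotype stays an open explanation that these 4 libraries do not test further.

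Osteoblast and collagen lists were called lower in cKO; all 45 tested members of both, leaving out odontoblast markers, were used here. If less odontoblast RNA were the cause, the difference between the cHet libraries would be 0.95 times the group difference, as for Dspp. The remainder, relative to each member's mean, had a median of -0.2 (quartiles -0.58 and 0.1), so less odontoblast RNA cannot be told apart from the group difference at this spread. For less RNA from dental epithelium, the members lay in cKO_1, where 13 of 23 well-expressed epithelium markers exceeded both cHet libraries, at a median of -0.2 (quartiles -0.55 and 0.19) from the cHet mean on the log2 scale; without cKO_0 the epithelium list was called higher (median 1.08) and the collagen list lower (median -0.36), but this rests on 1 cKO library and the explanation stays open. Transcripts of odontoblast and epithelial marker genes were present in every library, although the cells were sorted for tdTomato. Whether such cells carried the reporter or escaped the sort was not tested. Ambn ranged from 165600 to 976100 and Dspp from 229.5 to 69630. The genotype stays open and untested.

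Interferon response genes lay higher in cKO. Low complexity of cHet_1 stays open. Without that library the list was still called at camera's preset correlation (adjusted p = 4.48e-05), with a median of 0.59 against 0.82 with all libraries. Only cHet_0 then stands for its group, so this fit cannot decide. With all libraries the call was not kept with an estimated correlation (adjusted p = 0.7). That result includes cHet_1 and does not bear on this explanation. RNA from endothelial cells cannot be told apart from a change within the sorted cells: without cKO_1, the library with most endothelial transcripts, the interferon median was 0.97 while the endothelial median was 0.11, but the interferon list no longer passed (adjusted p = 0.0545). Pecam1 was listed at 299.5 and 1278 in the cKO libraries, although the cells were sorted for tdTomato. Whether endothelial cells carried the reporter or escaped the sort was not tested. The genotype stays open.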
